A study of Homo sapiens with 12 samples.

How the data were processed

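N6-methyladenosine (m6A) was mapped by eCLIP with an m6A antibody in WI-38 cells, a diploid fibroblast line from fetal lung. Per the labels' protocols, total RNA of proliferating cells at population doubling level 22 and of cells made senescent by 10 Gy of ionizing radiation and harvested 10 days later was broken chemically into short fragments, crosslinked to the antibody with UV light, immunoprecipitated, and made into libraries by adapter ligation, reverse transcription and PCR. The 3 immunoprecipitated libraries of each state were used. The 6 input libraries were not analysed here as separate samples. The titles gave the groups and replicate numbers. The cell line tag of proliferating replicate 3 and of senescent replicates 1 and 2 read WI-39, WI-40 and WI-41, while their protocols named WI-38, so all 6 libraries were kept and the 3 tagged WI-38 were also analysed alone.

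Each library had its own peak list, so peaks were called per library and not on pooled samples. The deposited log2 fold of a peak is its enrichment over a background that the file does not name, as the authors computed it, and no listed value was below 3. The deposited -log10 p-value of a peak comes from the authors' own peak test, per the file headers, and was capped at 400. Gene symbol, Ensembl gene identifier and transcript feature of each peak are also the authors'. Coordinates are on hg38, per the submitters' processing notes. The aligner, the peak caller, the filters and the annotation version are not given in the sources used here. The folds and p-values were used only to describe, rank or filter peaks within a list. Peaks did not overlap within a library, and neighbouring peaks often shared a boundary. Start positions were read as counted from 0 and are printed counted from 1.

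The lists give no read counts, so read depth per library is unknown, and no interval from counting was computed. Whether a peak was called depends on the amount of the transcript and on depth as well as on methylation, and these were not separated here. Peaks that named several genes (1232 peaks, 1.27%) and 33 peaks with no gene were left out of gene tests. Of the 8661 gene symbols, 7755 were found in the RefSeq table of the assembly GRCh38.p14, which was used only for the spans of named genes.

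Lists were compared by overlap of at least 1 base on the same strand. Peaks of all libraries were joined into union regions, and regions and genes called in 3 of 3 libraries of one state and 0 of 3 of the other were counted. The number of peaks per gene was tested with limma (lmFit, then eBayes with trend and robust) on log2 of peaks plus 0.5, divided by all peaks in genes of that library plus 1, times 1000, for 6155 genes with at least 3 peaks over the 6 libraries. The threshold was a Benjamini-Hochberg adjusted p of 0.05. On this scale a gene with the same number of peaks in every library lies below 0, because senescent lists were longer. Gene lists fixed before the data were examined were tested with camera at an inter-gene correlation of 0.01, where at least 3 members were tested, and again with an estimated correlation. Single values per library were compared with a two-sided exact permutation test over the 10 splits of the 6 libraries, which cannot give a p below 0.1. The labels do not say that replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical.

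Most of the genes named were set by a rule fixed before the data were examined. PTCHD4 was always named. In each direction the rule took the 10 genes with the largest absolute log2 fold change past the threshold, filled up from genes with peaks in all 3 libraries of one state and none of the other, ranked by their lowest number of peaks in that state and then by total peaks. It also took the members of the m6A machinery list, up to 4 members of every other list by absolute log2 fold change, and the 5 genes with the most peaks. Outside this rule, H2BC8, TNC and ITGA5, and AC021134.1, ALK, NTRK3, RET, ROS1, BCOR and EZH2 among the regions of high fold, were chosen after their values were seen.

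The limma step was tested on simulated peak numbers with Poisson noise for this comparison, with 200 genes changed in each of 5 draws and about 6089 genes tested. The changed genes were drawn only from genes with at least 12 peaks over the 6 libraries. Of these it recovered 6.20% of genes changed 2-fold and 39.4% of those changed 4-fold, and 4.60% of its calls were false. Recovery among genes with 3 to 11 peaks was not simulated. The simulation also left out the division of regions into adjoining peaks and any spread between replicates beyond Poisson noise. These rates may therefore not hold for the real lists. Alternatives were leaving out each library, the replicate number as a block, other filters, offsets and scalings, limma without trend, stricter folds (log2 above 3.507) or p-values (-log10 of at least 4), lists reduced to the shortest length of 9963 peaks, other overlap rules, and the 3 libraries tagged WI-38. Reduced lists kept their peaks of highest fold, so the fold cutoff rose in the longer lists. Merging adjoining peaks and leaving out regions with a log2 fold of 6 or more were added after the data had been seen. A motif analysis needs a genome sequence and was not run. Software was Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1.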

Results

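The data comprised 6 lists of m6A-eCLIP peaks, short stretches of RNA recovered with an antibody against N6-methyladenosine, from WI-38 fibroblasts. Replicates 1, 2 and 3 of proliferating cells had 17463, 15397 and 9963 peaks, and those of cells made senescent with 10 Gy of ionizing radiation had 17238, 15684 and 21301. The means were 14274 ± 3874 and 18074 ± 2900 (SD, n = 3 each), a difference of 3800 that was within the spread between libraries (two-sided exact permutation p = 0.3, smallest possible 0.1). After adjoining peaks were merged, the means were 8827 ± 2047 and 11284 ± 1119 regions (SD, n = 3), and the groups did not overlap (exact permutation p = 0.1). Peaks were found in 5019 ± 757 genes per proliferating library and 5906 ± 393 genes per senescent library (SD, n = 3, exact permutation p = 0.1). Read depth behind the lists was unknown.

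The series was designed to ask about m6A in PTCHD4, a gene of the patched-domain family. PTCHD4 (ENSG00000244694.7, chromosome 6, minus strand, hg38) had 2, 1 and 3 peaks in the proliferating libraries and 6 peaks in each senescent library. The means were 2 ± 1 and 6 ± 0 (SD, n = 3), and the groups did not overlap (exact permutation p = 0.1, the smallest possible, and a separation of 3 against 3 that chance gives in 10% of cases). Scaled to the length of each list, the log2 fold change was 1.09 ± 0.44 (SE), which did not pass the threshold over all genes (limma adjusted p = 0.335). Leaving out 1 library moved it from 0.69 (without proliferating replicate 2) to 1.62 (without proliferating replicate 3). When adjoining peaks were merged, PTCHD4 had 2, 1 and 3 regions in proliferating libraries and 3, 4 and 4 in senescent ones, and the log2 fold change was 0.43. The exact permutation p was then 0.2, as it was with lists reduced to the shortest length (a difference of 2.33 peaks).

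The main PTCHD4 region lay in coding sequence at 47878470 to 47878876 and was called in 2 of 3 proliferating and 3 of 3 senescent libraries. Its highest authors' log2 fold was 3.20 and 3.21 in the proliferating lists that held it, and 4.23, 4.25 and 4.51 in the senescent lists. A neighbouring coding region at 47878954 to 47879043 was called in 0 of 3 proliferating and 3 of 3 senescent libraries, with log2 folds of 3.28, 3.47 and 3.07. A coding region at 48068240 to 48068366 was called in 2 of 3 libraries of each state. The other 4 PTCHD4 regions were each called in 1 library, among them a 3′ UTR region at 47878245 to 47878279 in senescent replicate 3. A coding region at 47879149 to 47879185 held the only PTCHD4 peak of proliferating replicate 2, with a log2 fold of 4.77, the highest of any PTCHD4 peak. Its authors' -log10 p was only 3.695, under the stricter limit of 4. The main region reached 11.09 and 3.667 in the proliferating lists that held it, and 400, 400 and 85.9 in the senescent lists. The folds are each list's own and were not tested between lists. Transcript amount and read depth were not separated from methylation, so the higher PTCHD4 peak number may reflect any of them.

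**Figure D1:**
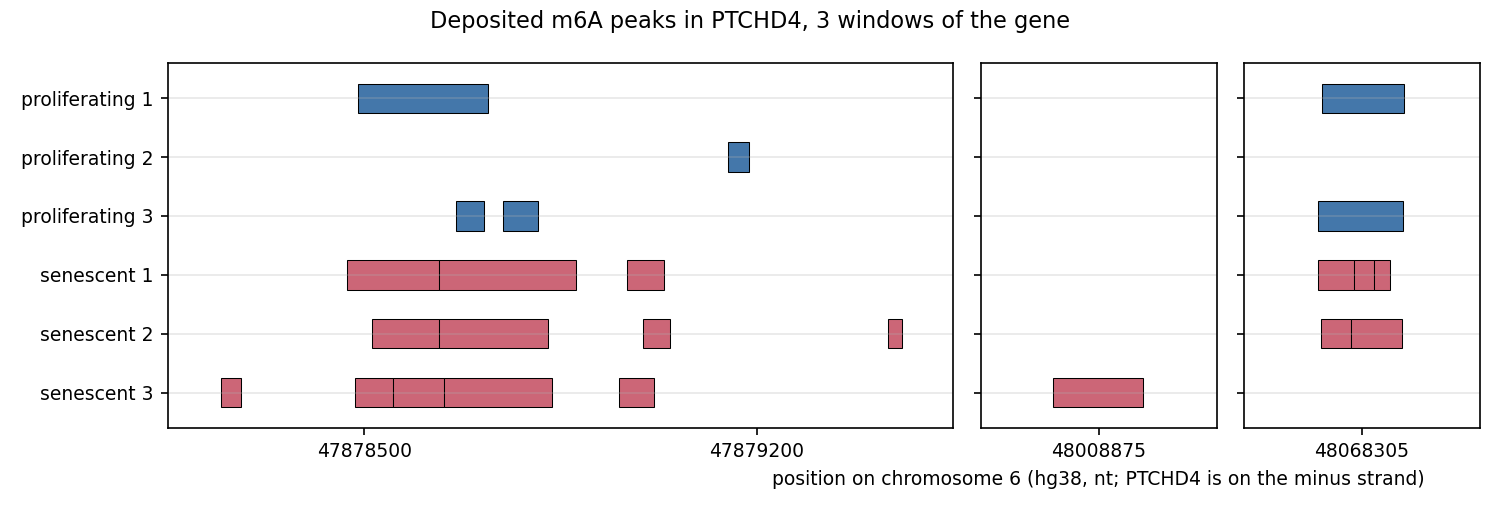
Peaks of PTCHD4 in each library along 3 windows of chromosome 6 (hg38 position in nt on the horizontal axis, 1 row per library, proliferating in blue and senescent in red, each box 1 deposited peak). The region at 47878954 to 47879043 has a peak in all 3 senescent and none of the proliferating libraries.

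At the level of the transcriptome, peak lists overlapped nearly as much across states as between replicates of one state. The share of the smaller list's peaks that overlapped a peak of the other list averaged 72.7% for pairs of libraries of one state and 71.1% for pairs across states, a difference of 1.56 percentage points (exact permutation p = 0.1, smallest possible). Coding sequence held 45.2% ± 0.224 of peaks in proliferating and 44.3% ± 0.594 in senescent libraries (SD, n = 3), and 3′ UTRs held 37.0% ± 2.11 and 37.6% ± 0.673. Noncoding exons held 7.15% ± 0.582 and 7.82% ± 0.197, with no overlap between the groups. Since the smallest possible p was 0.1, which noncoding exons reached, none of the 6 feature classes could pass the threshold. The test therefore cannot show that the shares were alike (exact permutation p from 0.1 to 0.9, Benjamini-Hochberg adjusted 0.6 to 0.9). IGFBP5, which encodes a secreted binding protein for insulin-like growth factors, had the most peaks, 46.0 ± 8.72 and 54.0 ± 6.56 per library (SD, n = 3), with a log2 fold change of -0.13 (limma adjusted p = 0.793). LPAR1, CKAP4, PCDH18 and CD248 followed, and none of them passed the threshold.

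Genes with peaks in all 3 senescent and no proliferating libraries numbered 167, and the reverse held for 50 genes. Those with peaks only in senescent libraries included MAP3K7, a kinase of stress and inflammatory signalling, with 2, 4 and 5 peaks, and SDC3, a cell-surface proteoglycan, with 5, 2 and 4 peaks. COLEC10, PLEKHM2, ZDHHC23, CLCA4-AS1, GAB3 and RBM33 were the next by the same ranking. Those with peaks only in proliferating libraries included CLSPN, which acts in the replication checkpoint, with 3, 3 and 2 peaks, XRCC2, a homologous recombination protein, with 2, 3 and 2 peaks, and ITPRIPL1, with 5, 2 and 2 peaks. Of 23394 union regions, 370 were called in all senescent and no proliferating libraries and 102 in the reverse pattern. Once every list was reduced to its 9963 peaks of highest log2 fold, the length of the shortest list, the regions numbered 180 and 138, and 85 genes were found in each direction. This also raises the fold cutoff in the longer lists. Random draws of 9963 peaks per list gave medians of 99.5 genes on the senescent and 69 on the proliferating side. With at least 2 peaks per library 19 and 6 genes were left, and the stricter fold left 32 genes and 41 regions on the proliferating side. Leaving out 1 library, which eases the requirement, gave 215 (without proliferating replicate 3) to 374 (without proliferating replicate 1) and 72 (without senescent replicate 2) to 130 genes (without proliferating replicate 3). Regions then numbered 463 and 384 without proliferating replicate 3 and 918 and 154 without senescent replicate 2, which were the ends of both ranges. In the libraries tagged WI-38 alone, 2 proliferating and 1 senescent, the genes numbered 1144 and 375 and the regions 5352 and 1013.

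Testing of peak numbers per gene found 2 genes with more and 7 with fewer peaks in senescent cells among 6155 genes (limma, adjusted p below 0.05), and 648 genes had an unadjusted p below 0.05. NEAT1, a nuclear long noncoding RNA that builds paraspeckles, rose from 1.33 ± 1.53 to 13.3 ± 1.15 peaks per library (SD, n = 3), a log2 fold change of 2.96 ± 0.43 (SE, limma adjusted p = 0.000689). These peaks lay close together on chromosome 11 between 65424355 and 65424631, and once adjoining peaks were merged NEAT1 had 2, 1 and 0 regions against 2 in each senescent library, which did not pass the threshold. At 65424355 to 65424461 the highest log2 fold was 3.09 in proliferating replicate 1 and 4.11, 4.09 and 4.51 in the senescent lists. At 65424532 to 65424631 it was 3.41 and 3.43 in proliferating replicates 1 and 2, and 3.91, 4.12 and 4.92 in the senescent lists. All of these reached the -log10 p cap of 400. The proliferating folds lay near the lowest listed value of 3, so the NEAT1 peak number depends on that limit. GALNT5, a glycosyltransferase, rose from 10.0 ± 3.61 to 28.7 ± 8.14 peaks (log2 fold change 1.13 ± 0.24, limma adjusted p = 0.0454), and its merged log2 fold change was -0.54.

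The genes that fell included FAM111B, a protease-domain protein linked to DNA replication, with 7, 5 and 4 peaks in proliferating libraries and none in senescent ones (limma adjusted p = 0.00208), and ERCC6L, a mitotic DNA translocase, with 10, 7 and 6 against 0, 0 and 1 peaks (adjusted p = 0.000654). CKAP2L, a mitotic spindle protein, had 5, 2 and 4 peaks against none (adjusted p = 0.0390), and VPS28, a part of the ESCRT-I complex, had 2, 4 and 7 against none (adjusted p = 0.0390). RGS3, a regulator of G-protein signalling, fell from 5.33 ± 0.577 to 0.667 ± 0.577 peaks (SD, n = 3, limma adjusted p = 0.0199). PLEKHO1 fell by 1.87 and IER5, an immediate early response gene, fell by 1.82 on the log2 scale (limma adjusted p = 0.0408 and 0.0436). FAM111B, ERCC6L and CKAP2L also passed the threshold after adjoining peaks were merged. The count of 2 higher and 7 lower depended on scaling, with 2 and 2 after scaling to the median gene and 0 and 0 without scaling, and it was 1 and 0 without proliferating replicate 3, 1 and 4 without proliferating replicate 2, and 2 and 13 without senescent replicate 1. Without proliferating replicate 1 it was 5 and 4, and with the stricter fold 3 and 9, and these calls shared 4 and 3 genes with the 9.

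**Figure D2:**
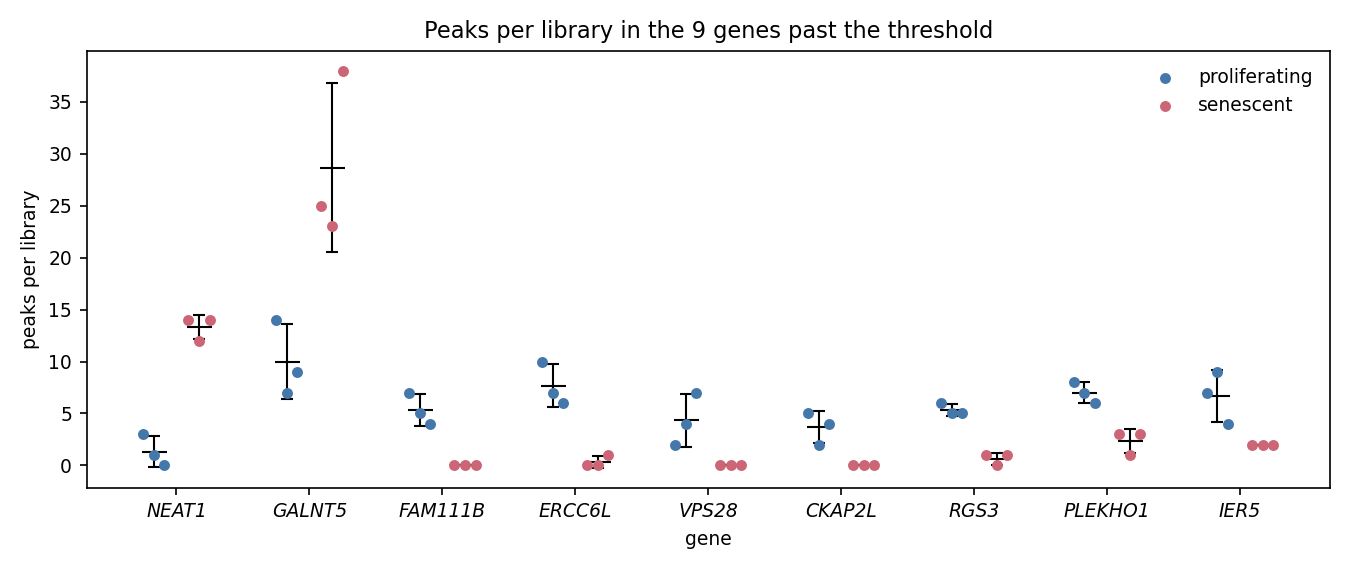
Peaks per library (vertical axis) in the 9 genes past the threshold, proliferating in blue and senescent in red, with 1 point per library and the mean ± SD of 3 libraries in black. Senescent libraries held 12 to 14 peaks in NEAT1 and none in FAM111B, VPS28 and CKAP2L.

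Among gene lists, replication-dependent histones rose and genes of proliferation and the cell cycle fell at camera's preset correlation. With an estimated correlation neither list passed (adjusted p = 0.156 for both). All 9 tested histone genes had log2 fold changes above 0 (median 1.21, camera adjusted p = 0.000318, and 0.156 with an estimated correlation), and 4.67 ± 2.52 of 59 histone genes had a peak per proliferating library against 11 ± 0 per senescent library (SD, n = 3). H2BC8 had 4, 3 and 4 against 10, 11 and 15 peaks, and H2AC13, H2AC17 and H4C8 had peaks in all senescent and no proliferating libraries. Histone genes of the same family are closely similar in sequence, so the gene each peak was assigned to is uncertain. This was not tested. Of 15 tested cell cycle genes 13 were below 0 (median -0.99, camera adjusted p = 0.00128, and 0.156 with an estimated correlation). The cell cycle call was also lost without proliferating replicate 1 (adjusted p = 0.0645), with lists reduced to the shortest length (mean -0.41, adjusted p = 0.461) and with the stricter fold (mean -0.47, adjusted p = 0.597). Of 60 cell cycle genes, 12.7 ± 5.13 had a peak per proliferating library and 10.0 ± 3.46 per senescent library (SD, n = 3), and the groups overlapped. MKI67, a marker of cycling cells, had 6, 7 and 2 against 0, 2 and 1 peaks, UHRF1 had 3, 6 and 0 against none, and BRCA2 had 3, 1 and 2 against none. No single member of either list passed the threshold over all genes. Adjusted over the list alone, H2BC8 was higher and AURKA, BRCA2, MKI67 and UHRF1 were lower.

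Transcription factors of the immediate early response and genes of the extracellular matrix fell, and interferon genes rose, each relative to all tested genes and at camera's preset correlation. With an estimated correlation none of the 3 lists passed (adjusted p = 0.156 for each). Of 17 immediate early genes 14 were below 0 (median -0.45, camera adjusted p = 0.00188), with IER5 past the threshold and IER5 and JUND lower when adjusted over the list alone. Without scaling the median of this list was -0.080 and its mean -0.15, still past the threshold (adjusted p = 0.0183), and with adjoining peaks merged the call was lost (adjusted p = 0.0697). Of 28 matrix genes 18 were below 0 and 10 above it (median -0.38, camera adjusted p = 0.0138). The median was close to -0.37, the value of RPL28, a ribosomal protein gene with 1 peak in every library. The 4 largest absolute changes were -2.13 for LOXL1 and 1.30, 1.09 and 1.03 for DCN, VCAN and COL1A1, none past the threshold over all genes. TNC, LOXL1 and ITGA5 were lower when adjusted over the list alone. TNC, the matrix glycoprotein tenascin C, had 39, 37 and 19 against 25, 15 and 25 peaks. The matrix call was lost without scaling, where the mean was 0.10 on the log2 scale, without proliferating replicate 1 (adjusted p = 0.0768) and without senescent replicate 2 (adjusted p = 0.0627), and it held in 12 of 21 alternatives (adjusted p from 0.00406 to 0.341). Of 7 interferon genes 6 were above 0 (median 1.22, camera adjusted p = 0.0237), among them IFI27 with 3, 2 and 1 peaks and IRF1 with 1 in each senescent library, and neither with a peak in proliferating libraries. Only 7 of the 16 interferon genes with a peak in any library were tested. With a filter of 1 peak the list mean was 0.19 against 0.88, and the call was lost (camera adjusted p = 0.327). The interferon call was also lost without any one of 5 of the 6 libraries, and it held in 9 of 21 alternatives.

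**Figure D3:**
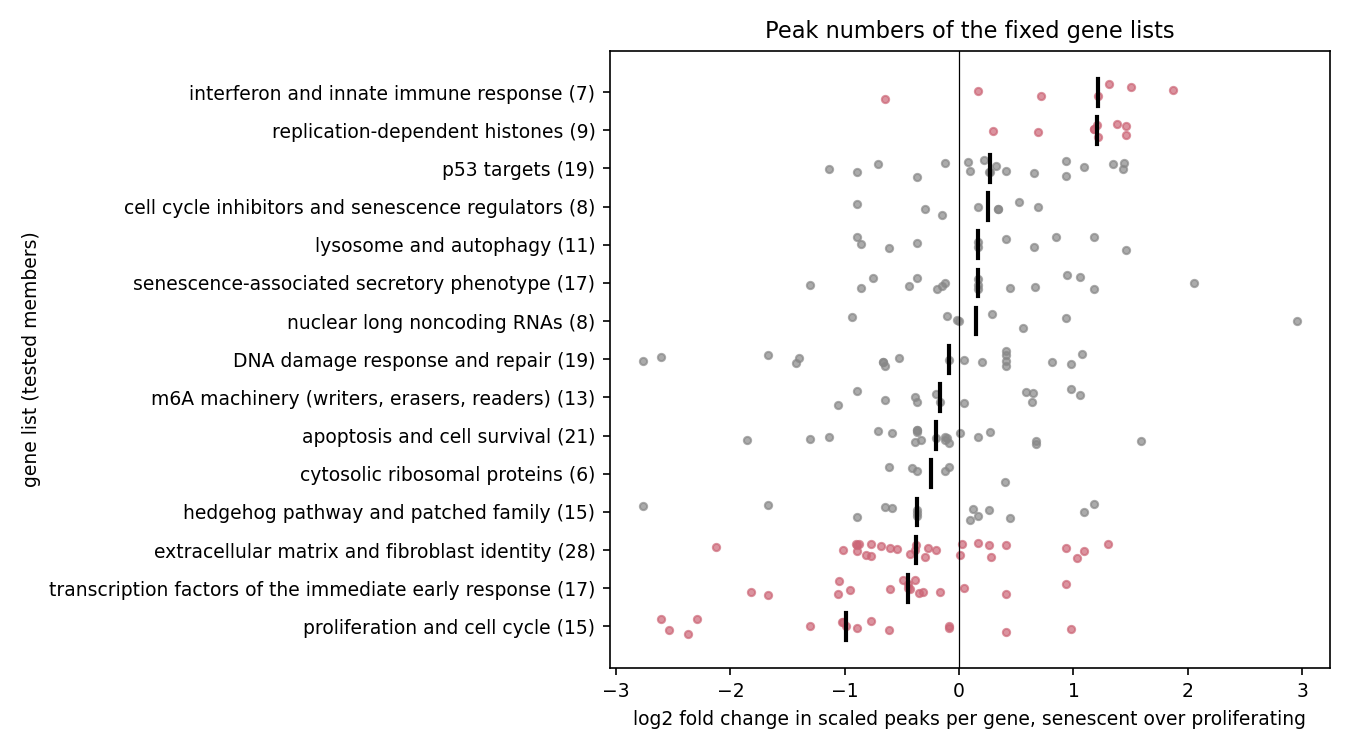
Log2 fold change in scaled peak number, senescent over proliferating (horizontal axis), of each tested member of the fixed gene lists (1 point per gene, black bar at the list median, red where the camera adjusted p was below 0.05). All 9 histone genes lie above 0 and 13 of 15 cell cycle genes lie below 0.

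The other 10 tested lists did not pass the threshold. Of 19 p53 target genes 14 were above 0 (median 0.27, camera adjusted p = 0.118), with PPM1D at 1, 1 and 0 against 2, 5 and 3 peaks and TRIAP1 at 3, 1 and 0 against 4, 4 and 5. The p53 list did pass with lists reduced to the shortest length (mean 0.90 against 0.33, adjusted p = 0.0145), with the stricter fold (adjusted p = 0.00903), with filters of 1 or 6 peaks (0.0329 and 0.0347) and without senescent replicate 1 (0.0416). The secretory phenotype had 9 of 17 genes above 0 (adjusted p = 0.710), and FGF7, a growth factor, was higher when adjusted over the list alone, with 3, 1 and 0 against 6, 6 and 9 peaks. The m6A machinery had 6 of 13 tested genes above 0, with a median of -0.17 and a mean of 0.016 (camera adjusted p = 0.744). YTHDF2, a reader of m6A, had 8, 6 and 6 against 8, 7 and 8 peaks, and METTL3, the catalytic writer, had 1 peak in each of 2 senescent libraries and was not tested. Camera adjusted p was 0.191 for DNA repair, 0.358 for apoptosis and survival, 0.710 for cell cycle inhibitors, 0.710 for ribosomal proteins, 0.532 for the hedgehog and patched families, 0.690 for lysosome and autophagy, and 0.118 for nuclear long noncoding RNAs, which passed at the shortest length, with the stricter fold and with a filter of 1 peak. Adjusted over the list alone, BLM and BRCA2 (repair), BCL2 (survival) and GLI1 (hedgehog) were lower and NEAT1 was higher. Of markers of other cell types, 2 of 12 endothelial, 1 of 16 epithelial (CLDN4), 1 of 16 immune (CD14, in senescent libraries only) and 0 of 12 neural and muscle genes had a peak in any library, and 0 of 15 mitochondrially encoded genes did.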

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

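Merging adjoining peaks and leaving out regions of high fold were chosen after the data had been seen, and all other alternatives before. The cause of a change was not tested unless stated. The planned motif analysis was not run. Read depth was unknown and its effect could not be measured. PTCHD4 kept its direction under every alternative run, with a difference of 1.67 to 5 peaks or regions. Apart from the libraries tagged WI-38, its exact permutation p rose from 0.1 only with lists reduced to the shortest length (0.2, difference 2.33) and with adjoining peaks merged (0.2, difference 1.67). In the libraries tagged WI-38, with a lone senescent library, the difference was 4.5 peaks. List means below are on the log2 scale, and a list's direction is that of camera's test against all other genes, so it can turn while the mean keeps its sign.

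The replicate numbers did not pair the samples (correlation of deviations -0.079, 0.015 and 0.0057). With the replicate block, 2 genes were higher and 9 lower, the 9 called genes of the unblocked fit were among these 11, and the same 5 lists passed.

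Genes higher and lower in senescent libraries numbered 11 and 24 with at least 1 peak over the libraries, 1 and 3 with at least 6 peaks, 4 and 28 with an offset of 1, 0 and 0 with an offset of 0.1, 0 and 0 with no scaling, 2 and 2 with scaling to the median gene, 0 and 1 with no trend, 3 and 9 with the stricter fold, 1 and 7 with stricter p, 1 and 0 with lists reduced to the shortest length, 0 and 4 with adjoining peaks merged, 1 and 7 without regions of high fold, and 2 and 29 with the libraries tagged WI-38, where the lone senescent library is assumed to vary like the proliferating ones. Where no gene was called, 627 genes (offset of 0.1) and 709 genes (no scaling) had an unadjusted limma p below 0.05. The median of all genes moved from -0.00092 to 0.37 with no scaling and to 0.12 with scaling to the median gene. Leaving out 1 library gave 1 to 5 higher and 0 to 13 lower genes. Of the calls, 9 of 35 with at least 1 peak, 9 of 32 with an offset of 1, 3 of 12 with the stricter fold, 3 of 4 with merged peaks and 7 of 31 with the libraries tagged WI-38 were among the 9 genes. Without proliferating replicates 1, 2 and 3 in turn these were 4 of 9, 4 of 5 and 1 of 1, and without senescent replicates 1, 2 and 3 they were 9 of 15, 6 of 7 and 6 of 9. In the remaining unblocked alternatives with calls, every called gene was among the 9.

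Genes present in all senescent or all proliferating libraries alone numbered 85 and 85 with lists reduced to the shortest length and 19 and 6 with at least 2 peaks per library. They numbered 168 and 32 with the stricter fold, and 1144 and 375 with libraries tagged WI-38. Regions numbered 180 and 138 at the shortest length, 41 on the proliferating side with the stricter fold, and 5352 and 1013 with libraries tagged WI-38, where fewer libraries must hold a region. Leaving out 1 library gave 215 to 374 and 72 to 130 genes, and 463 to 918 and 154 to 384 regions. The overlap difference was -5.15 points with libraries tagged WI-38, from 1 pair within a state.

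With an estimated correlation 0 lists passed, at unchanged means of -0.26 (matrix), 0.88 (interferon), -1.01 (cell cycle), 1.12 (histones) and -0.52 (immediate early). Merged peaks left 2 lists, and the means were -0.34 (matrix), 0.60 (interferon) and -0.45 (immediate early) for those lost. Libraries tagged WI-38 left 3 lists, with -0.23 (matrix) and 0.91 (interferon) lost. The stricter fold lost matrix (-0.066), interferon (0.25) and cell cycle (-0.47), and the shortest length lost matrix (-0.095), interferon (0.65) and cell cycle (-0.41). Both settings had 4 lists past the threshold, because p53 targets (0.69 with the stricter fold, 0.90 at the shortest length) and nuclear long noncoding RNAs (0.77 and 0.82) were gained. With at least 1 peak, p53 targets (0.33) and noncoding RNAs (0.35) were gained, as were p53 targets with at least 6 peaks (0.54) and without senescent replicate 1 (0.53). Without proliferating replicate 1, the matrix, interferon and cell cycle calls were lost, and without senescent replicate 2 the matrix and interferon calls. Interferon was also lost with at least 1 peak (0.19) or at least 6 (0.82), and matrix with no scaling (0.10) and with no trend (-0.26). Leaving out 1 library left 2 to 5 lists, with means of -0.38 to -0.23 for matrix, 0.70 to 1.00 for interferon and -1.20 to -0.97 for cell cycle.

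Lists and genes that changed direction had not passed the threshold, except GALNT5 (-0.54 with merged peaks). The stricter fold turned hedgehog (-0.049), lysosome (-0.17), secretory phenotype (-0.26), LPAR1 (0.0026), RBM15 (0.58), YTHDC1 (0.19) and the share of other features (-0.15 points). The shortest length turned cell cycle inhibitors (0.018), lysosome (0.012), m6A machinery (0.11), secretory phenotype (-0.20), IGFBP5 (0.027), RBM15 (0.032) and the intron share (0.30 points). Libraries tagged WI-38 turned DNA repair (-0.049), cell cycle inhibitors (-0.40), LPAR1 (0.016), RBM15B (-1.17) and ZC3H13 (0.48). No scaling turned m6A machinery (0.38), secretory phenotype (0.52), CD248 (0.20), CKAP4 (0.062), IGFBP5 (0.24), LPAR1 (0.27), YTHDF2 (0.20) and ZC3H13 (0.16). Scaling to the median gene turned LPAR1 (0.014) and an offset of 1 turned RBM15B (-0.14). Merged peaks turned m6A machinery (-0.14), CD248 (0.21), IGFBP5 (0.085) and WTAP (-0.22). Leaving out 1 library gave -0.017 to 0.38 for cell cycle inhibitors, -0.087 to 0.12 for m6A machinery, -0.011 to 0.26 for secretory phenotype, -0.31 to 0.015 for ribosomal proteins, -0.85 to 0.074 for RBM15, -0.51 to 0.76 for RBM15B, -0.75 to 0.43 for ZC3H13, -0.31 to 0.033 for LPAR1, -0.31 to 0.0048 for YTHDF2 and -1.26 to 0.13 for PCIF1, and -0.042 to 0.13 points for other features, -0.35 to 1.74 for 3′ UTRs and -0.52 to 0.37 for 5′ UTRs. Of 1233 gene values under alternatives, 1096 kept their direction and side of the threshold, as did 262 of 314 list values. Most of these belong to genes and lists that had not passed, so the shares do not measure how stable the calls were. Of 21 alternatives, the call held in 12 for matrix, 9 for interferon, 17 for cell cycle, 20 for histones and 19 for immediate early genes.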

Other observations

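The tests of NEAT1, of few reads, of a state difference in the number of regions of high fold, and of other splits for genes present in one state were chosen only after the result was seen, and the panel, list length, merged gene and remaining split tests were set before, except that the interval over genes was added once the merged gene value was known. The share of regions was added once the number of regions of high fold was known.

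Regions with an authors' log2 fold of 6 or more formed a class of their own. There were 212 such regions, of which 31 were called in all 6 libraries and 114 in 1 library. Their median width was 21 to 23 nt per library against 76 to 85 nt for other regions. The highest, with a log2 fold of 11.17, lay in an intron of the noncoding gene AC021134.1 on chromosome 4 at 162763729 to 162763750. ALK, NTRK3, RET and ROS1, which encode receptor tyrosine kinases, held such regions in all 6 libraries.

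A candidate explanation for these narrow regions is carry-over of sequences from a cancer gene panel, and no panel is named in the labels. Panel genes that had not been seen before made up 10 of 171 genes with such regions and 31 of 8484 others (odds ratio 16.9, 95% confidence interval 7.27 to 36.1, Fisher's exact p = 4.60e-09), and the odds ratio was 13.5 without BCOR and EZH2, which had been seen in other tables. The number per library was 61 to 75 in proliferating and 95 to 112 in senescent cells, a gap of 20 regions that a difference between the cell states was taken to predict. As a share of all merged regions of a library the groups overlapped, at 0.694% to 0.942% and 0.755% to 1.06%, so a state difference in number and longer lists cannot be told apart, and a state difference in width was not tested. Folds inflated by few reads over an almost empty background stay open, since the median -log10 p of these regions was above that of the others in 5 of 6 libraries and below it in senescent replicate 2 (19.1 against 24.3).

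The excess of genes with peaks in all senescent and no proliferating libraries may come from list length. Over 100 random draws of equal length the median ratio of both counts was 1.41 (0.942 to 1.91), against 3.34 in the deposited lists. Methylation that differs between the states stays open as a contributor and was not tested apart from transcript amount.

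The NEAT1 call could reflect the same enriched region being divided into more adjoining peaks. Its mean number of peaks differed by 12 and its mean number of merged regions by 1, which lies between the bounds set for and against that explanation. For the other 8 called genes the median absolute log2 fold change of merged regions was 79.8% of that of peaks, past the bound of 75% set against the explanation, but with a bootstrap interval over genes of 29.3% to 94.3%. The 8 genes therefore do not decide it: GALNT5 turned to -0.54 and PLEKHO1 went from -1.87 to -0.38, the value of a gene with no change in its number of regions, while FAM111B stayed at -3.74 and ERCC6L at -3.62.

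The 10 splits of the 6 libraries are too few for a share under 0.05. The real split was the 1 split with the highest value in each of 4 counts: 9 genes past the threshold against at most 2 in another split, 5 gene lists against 1, 217 genes present in one state alone against 112, and 472 regions against 325.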
